A study of Zea mays with 10 samples.

How the data were processed

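The samples were maize kernels of the inbred line B73 (WT) and of an opaque-2 mutant in the B73 background (o2), grown in a greenhouse and taken 15 days after self-pollination. Polyadenylated RNA of dissected endosperm was sequenced in 3 WT and 3 o2 libraries, and chromatin immunoprecipitated with an antibody against the O2 protein was sequenced in 2 WT and 2 o2 libraries. The labels number the replicates and do not say whether they came from separate plants or ears, so all p-values measure the spread between these samples, which may be technical.

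Gene expression was deposited by the authors as RPKM, read numbers scaled to gene length and library size, with 28580 gene IDs and 1 column per RNA library. The submitters' processing notes name Trimmomatic, TopHat2 2.0.9, bedtools 2.17.0, edgeR 3.2.4, Bowtie2 2.1.0, MACS2 2.1.0.20140616 and the genome build B73 RefGen_v3, without roles or order. Which read classes were counted, whether strand was used and how the scale factor was set are not given in the sources used here. The deposited RPKM columns had medians between 1.56 and 1.60, while their sums ran from 207265 to 2588142. Steps in the lowest values gave the worth of 1 read in each library relative to WT replicate 1. By this measure, the number of reads per unit of RPKM was 0.69 of that library in WT replicate 3 and 1.54 of it in o2 replicate 1, whereas the uniquely mapped reads were 0.838 and 1.41 of it, so the scale was not the uniquely mapped read total alone. In the other libraries these steps were found in 90 to 188 of 1532 low genes, so reads were not recovered gene by gene and no count test was run.

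A second deposited table holds read counts per library by mapping class, deposited by the authors as counts of all, uniquely mapped, multiply mapped and unmapped reads. The third deposited file is 1 peak list for the whole series on B73 RefGen_v3. Per its file headers, it gives each peak's length, summit, pileup signal, −log10 p-value, −log10 q-value and fold enrichment ratio, all as deposited by the authors. The series design states that ChIP of B73 was set against B73 o2; whether replicates were pooled before peak calling is not given in the sources used here. These peak values are the authors' and serve only to describe and rank peaks within the list.

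For the RNA comparison, genes with an RPKM of 1 or more in at least 3 of the 6 libraries were kept, which left 18687. RPKM values were transformed to log2(RPKM + 0.1) and fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with trend), with genotype as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPKM + 0.1) scale and understate the change of low genes. Every adjusted p of a gene below is from this limma fit, or from its rerun under the alternative named with it. On simulated data with the same genes and the same spread per gene, the step recovered 48% of the genes changed by a log2 of 1, 84% of those changed by 2 or by 3 and 96% of those changed by 4, and 8.24% of its calls were false. The simulated noise was normal and independent between genes, whereas genes deviated together in the real libraries, so these rates may not hold for them. The limma fit on RPKM differs from a count-based analysis, which RPKM does not allow.

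Gene IDs were matched to names through a reference gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, used only for names. It paired 12658 of the 28580 IDs with a gene and gave 1766 of them a name beyond a locus or clone number. Of the paired IDs, 407 met 2 or more reference genes. Near-identical zein copies and overlapping gene models share reads, so values of single zein genes are uncertain. No genome or annotation of B73 RefGen_v3 was used here, so peaks were not linked to genes and were not searched for motifs.

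Before the data were examined, 17 gene lists, the tests, the rule for named genes and most alternatives were fixed. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, with Benjamini-Hochberg adjustment over 15 lists of at least 3 tested genes each. The 2 lists of 19-kDa and 22-kDa alpha zeins were added after the data were seen, and 6 matches to genes that only share a symbol were removed. No tested gene matched the lists of embryo-surrounding region markers, green maternal tissue markers and cytosolic ribosomal proteins, and the list of defence proteins had 2 tested genes, too few for a set test. Families were formed from shared symbol stems, since the names carry no product words, and tested with a one-sided Fisher's exact test for families of 5 or more tested genes.

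The named genes are o2 first; then, among called genes whose WT and o2 values do not overlap and whose higher group mean is 10 RPKM or more, the 12 largest falls and 12 largest rises that have a name; for each list the 4 members of highest mean RPKM, and in the zein, transcription factor, amino acid and carbon-nitrogen and starch lists up to 8 called members; and the 5 peaks of highest −log10 q. Genes outside this rule are said to have been chosen after their values were seen.

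The RNA libraries held 52906484 to 66795114 reads and the ChIP libraries 25580850 to 38299434, and the precision of each RPKM value is limited by this depth and by the number of replicates. Shares of summed RPKM and of mapped reads were compared with exact two-sided permutation tests, which cannot go below 0.1 with 3 libraries against 3 or below 0.333 with 2 against 2. Peak spacing was set against 1000 draws of uniform positions within the span of peaks on each chromosome. The share of peaks in the middle of the chromosomes carries an exact 95% binomial interval, which covers counting error only. These steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives were other pseudocounts and filters, median scaling, quantile normalization, a total without zeins, eBayes without trend or robust, the replicate number as a block, each library left out, stricter peak sets and larger families.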

Results

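Transcription in maize endosperm was compared between B73 (WT) and an opaque-2 mutant (o2) 15 days after pollination, and binding of the O2 protein was mapped by ChIP in the same genotypes. O2 is a bZIP transcription factor of the endosperm, known as an activator of storage protein genes. The RNA libraries held 52906484 to 66795114 reads and the ChIP libraries 25580850 to 38299434 reads. Multiply mapped reads made up 32.7% ± 5.88 (SD, n = 3) of the WT RNA reads and 21.2% ± 0.461 (SD, n = 3) of the o2 RNA reads, with no overlap between the groups (exact two-sided permutation p = 0.1, the smallest that this design allows). Uniquely mapped reads ranged from 28614800 in WT replicate 3 to 48169603 in o2 replicate 1 among the RNA libraries. In the ChIP libraries the uniquely mapped reads numbered 14444794 and 10611258 in WT and 11910627 and 8462481 in o2.

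The o2 gene itself (GRMZM2G015534) was nearly absent from the mutant RNA. Its level was 112, 86.1 and 163 RPKM in WT replicates 1 to 3 and 0.212, 0.173 and 0.254 RPKM in the o2 replicates. The mutant mean was 0.177% of the WT mean. The log2 fold change was -8.55 ± 0.25 (SE, n = 3 against 3; adjusted p = 4.36e-05), with the o2 values below the WT values in every library.

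Among named genes, storage protein genes had the largest falls in the mutant. Of 18687 genes tested with limma, 666 were called, of which 387 were lower and 279 higher in o2, and 522 of the calls were at least 2-fold. The 12 named genes with the largest falls were all alpha zeins, the main storage proteins of the endosperm, 10 of the 22-kDa class and 2 of the 19-kDa class. Of the called genes with a name and 10 RPKM or more in the higher group, 37 fell and 4 rose: DBP2 (GRMZM2G055204), the thioredoxin gene trh2 (GRMZM2G144653), agpsl1 (GRMZM2G163437) and GLK44 (GRMZM2G124540). DBP2 went from 5.0 ± 1.18 to 14.9 ± 1.56 RPKM (SD, n = 3 each; log2 fold change 1.58, adjusted p = 0.0130). The level of trh2 went from 13.0 ± 5.65 to 35.4 ± 2.41 RPKM (SD, n = 3 each; log2 fold change 1.52, adjusted p = 0.0467). GLK44 rose by a log2 fold change of 0.83 (adjusted p = 0.0418). Among the 215 called genes of 10 RPKM or more, 174 had no name, 81 of them lower and 93 higher. The WT and o2 values of all 666 calls did not overlap, and neither did those of 26.1% of all tested genes, where chance gives 10%.

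Left-out libraries moved the number of calls: it was 160 (120 lower) without WT replicate 1, 777 (378 lower and 399 higher, so that most were higher) without WT replicate 2, 451 (222 lower and 229 higher) without WT replicate 3, 290, 98 and 253 without o2 replicates 1, 2 and 3, and 299 without replicate 3 of both genotypes, an alternative chosen after seeing the data, while DBP2 was not called without any 1 of the o2 libraries (adjusted p up to 0.0657) and trh2 and GLK44 were each called in 1 of 6 such fits (adjusted p up to 0.170 and 0.166) and not with the replicate block (adjusted p = 0.0778 and 0.0933). Rescaling to a total without the zein lists moved the median log2 fold change of all tested genes from 0.05 to 2.08 and gave 17999 calls, 104 of them lower, whereas with 26 IDs that run parallel to zeins also left out of the total, an alternative chosen after seeing the data, the median was -0.03, 654 genes were called (429 lower) and 0 of the 666 calls changed sign, though trh2 and agpsl1 were no longer called (adjusted p = 0.0543 and 0.0516).

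Alpha zein transcripts fell in both size classes. All 12 tested 19-kDa alpha zein genes and 10 of 11 tested 22-kDa alpha zein genes were lower in o2, with median log2 fold changes of -8.31 and -10.10. Among the 22-kDa genes, z1C1_4 (GRMZM2G044625) went from 11673 ± 4787 to 9.99 ± 0.828 RPKM (SD, n = 3 each; log2 fold change -10.10, adjusted p = 4.36e-05), and z1C2 (GRMZM2G397687), the floury-2 gene, from 5636 ± 5134 to 4.16 ± 0.844 RPKM (SD, n = 3 each; log2 fold change -9.93, adjusted p = 0.00125). The 22-kDa gene not called was z1C1_11 (GRMZM2G088273), chosen after its values were seen, with a log2 fold change of -6.60 (adjusted p = 0.0608). The most abundant 19-kDa gene, z1A1_7 (GRMZM2G353268), had 117680 ± 90893 RPKM in WT and 459 ± 563 in o2 (SD, n = 3 each; log2 fold change -8.45, adjusted p = 0.0123). Its o2 values were 106, 162 and 1108 RPKM in replicates 1 to 3.

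Over the alpha zein lists, camera gave an adjusted p of 3.12e-28 for the 22-kDa class, 1.84e-17 for the 19-kDa class and 1.45e-12 for the 5 alpha zeins of the list fixed beforehand. None of these calls held with an estimated correlation, where the adjusted p was 0.105, 0.192 and 0.105. With fry the adjusted p was 0.000355, 0.00718 and 0.00052 in the same order, all downward. Adjusted over the list alone, 11, 12 and 5 of these genes fell. The 5 genes of the fixed list are also members of the 19-kDa or the 22-kDa list, so these tests are not separate support for each other. In o2 replicate 3, where the 19-kDa genes had a median of 218 RPKM against 13.7 and 15.5 RPKM in o2 replicates 1 and 2, the basal transfer layer markers had a median of 2.21 RPKM against 4.84 and 9.44 RPKM. When 1 library was left out, the 10 called 22-kDa genes were called in every fit but only 2 of the 12 19-kDa genes were: z1A1_7 was lost without WT replicate 1 (adjusted p = 0.0543) or o2 replicate 2 (adjusted p = 0.0753), and z1B_7, z1B_8 and z1B_9 were called only without o2 replicate 3 (adjusted p up to 0.173). Under quantile normalization and robust eBayes z1B_7 and z1B_8 were not called (adjusted p up to 0.0980), nor was z1B_7 with a pseudocount of 0.01 (adjusted p = 0.0515).

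**Figure D1:**
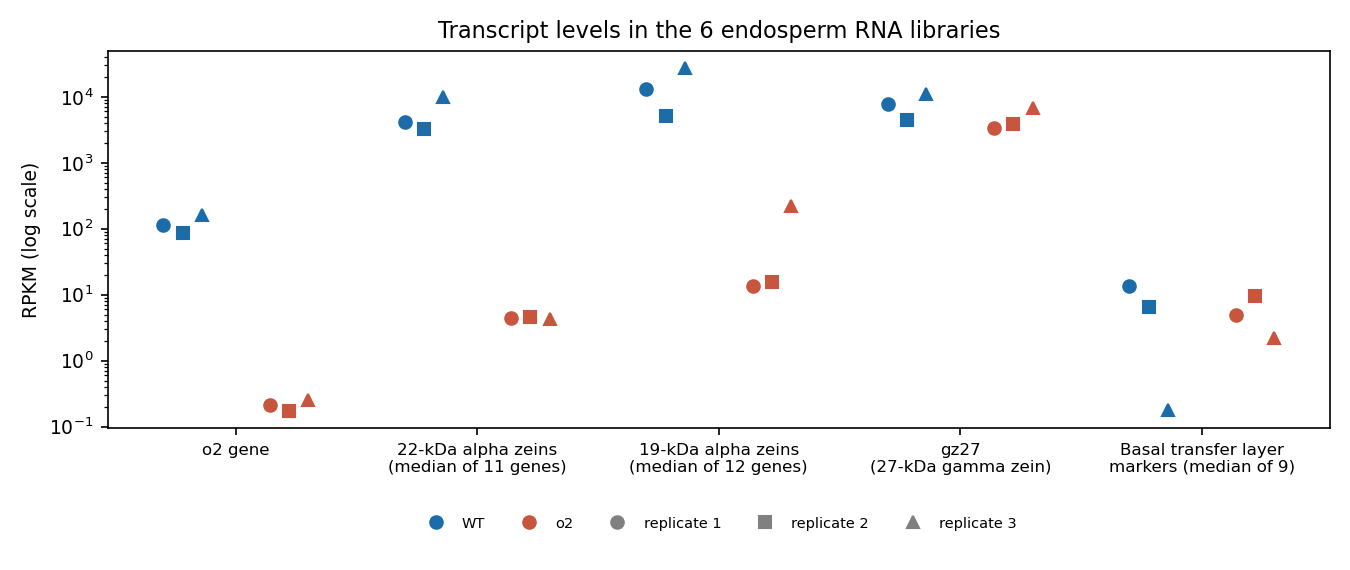
RPKM on a log axis of the o2 gene, the median 22-kDa and 19-kDa alpha zein gene, the gamma zein gene gz27 and the median basal transfer layer marker in each of the 3 WT (blue) and 3 o2 (red) RNA libraries, with 1 point per library and a marker shape per replicate. The median 22-kDa zein lies between 4.33 and 4.6 RPKM in the o2 libraries and between 3223 and 10041 RPKM in WT, and the median basal transfer layer marker is at 0.181 RPKM in WT replicate 3.

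The other zeins split. Of the 5 tested beta, gamma and delta zein genes, 2 fell and 3 were not called. The 15-kDa beta zein gene bz15 (GRMZM2G086294) went from 6117 ± 3027 to 27.7 ± 34.7 RPKM (SD, n = 3 each; log2 fold change -8.46, adjusted p = 0.00714), and the 18-kDa delta zein gene dzs18 (GRMZM2G100018) from 3739 ± 593 to 18.3 ± 7.64 RPKM (SD, n = 3 each; log2 fold change -7.73, adjusted p = 0.000138). The o2 values of bz15 were 7.62, 7.75 and 67.8 RPKM in replicates 1 to 3. The gamma zein genes had log2 fold changes of -0.72 (gz27, GRMZM2G138727, adjusted p = 0.546), -0.98 (gz16, GRMZM2G060429, adjusted p = 0.556) and -0.55 (gz50, GRMZM2G138689, adjusted p = 0.790). The list as a whole fell (adjusted p = 0.000342 in camera, 0.329 with an estimated correlation and 0.00718 in fry). Adjusted over the list alone, 2 genes fell. Under quantile normalization the list turned upward (camera adjusted p = 0.956) and gz27 was called higher, with a log2 fold change of 3.11 (adjusted p = 0.0102). Values of that step follow the rank of a gene in its library and not its RPKM level. Under the total without zein lists gz50 was called higher (1.58, adjusted p = 0.0413), below the median gene of that fit, and without o2 replicate 2 bz15 was not called (adjusted p = 0.0509).

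The 28 genes of the zein lists took 30.0% ± 3.22 of the summed RPKM in WT and 5.23% ± 2.87 in o2 (SD, n = 3 each), a difference of -24.7 percentage points. The exact two-sided permutation p was 0.1, the smallest that this design allows. The 22-kDa class went from 4.61% ± 0.963 to 0.023% ± 0.004 and the 19-kDa class from 23.4% ± 4.43 to 0.753% ± 0.894, while the beta, gamma and delta zeins went from 1.95% ± 0.272 to 4.46% ± 1.99 (SD, n = 3 each). The 19-kDa share was 0.181%, 0.296% and 1.78% in o2 replicates 1 to 3. The summed RPKM of the beta, gamma and delta zeins fell, from 25428, 15534 and 43617 in WT replicates 1 to 3 to 5868, 8033 and 17668 in o2. The total of all genes fell too, from 696998 or more in WT to 264780 or less in o2. With 26 further IDs whose values run parallel to a zein, found after the data were seen, the share was 83.6% ± 11.2 in WT and 12.2% ± 8.29 in o2 (SD, n = 3 each), a difference of -71.4 percentage points (exact two-sided permutation p = 0.1). These IDs were chosen for following a zein across both genotypes, so this difference is a description and its p-value is no test. Without the 10 highest genes outside the lists in the total, the difference for the zein lists was -56.4 percentage points. A share of summed RPKM is not a share of reads, since short gene models and overlapping copies count more.

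Of 11 tested genes of the list of amino acid and carbon-nitrogen enzymes, 2 of them for pyruvate phosphate dikinase, 3 fell, 0 rose and 8 were not called in limma. The list had a camera adjusted p of 4.22e-07 downward, and adjusted p = 0.0765 with an estimated correlation. Its adjusted p with fry was 0.00112, also downward. In these genes 8 were lower and 0 higher at an unadjusted p under 0.05, and 7 fell when adjusted over the list alone. The gene for the bifunctional lysine-degrading enzyme, lkrsdh1 (GRMZM2G181362), went from 11.8 ± 7.29 to 0.237 ± 0.116 RPKM (SD, n = 3 each; log2 fold change -5.04, adjusted p = 0.00433). The glutamine synthetase genes gln4 (GRMZM5G872068) and gln2 (GRMZM2G024104) fell, with log2 fold changes of -2.60 (adjusted p = 0.0330) and -1.37 (adjusted p = 0.0449). The pyruvate phosphate dikinase genes, PPDK2 (GRMZM2G097457) and Ppdk1 (GRMZM2G306345), did not pass, at 736 ± 204 against 229 ± 85.3 RPKM (SD, n = 3 each; adjusted p = 0.0585) and at 123 ± 51.8 against 36.8 ± 8.17 RPKM (SD, n = 3 each; adjusted p = 0.0501). PPDK2 passed under 4 and Ppdk1 under 10 of 18 alternatives (adjusted p from 0.0322 to 0.578 and from 0.0337 to 0.529). With 1 library left out, lkrsdh1 was called in all 6 fits, gln2 in 0 (adjusted p 0.0517 to 0.159) and gln4 in 2 (lost without WT replicate 1 or 3 or o2 replicate 2 or 3, adjusted p up to 0.124), and with the replicate block gln2 and gln4 were not called (adjusted p = 0.105 and 0.0683). Under the total without zein lists gln2 turned to 0.74, below the median gene of that fit, and gln4 was at -0.66 and not called (adjusted p = 0.230).

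**Figure D2:**
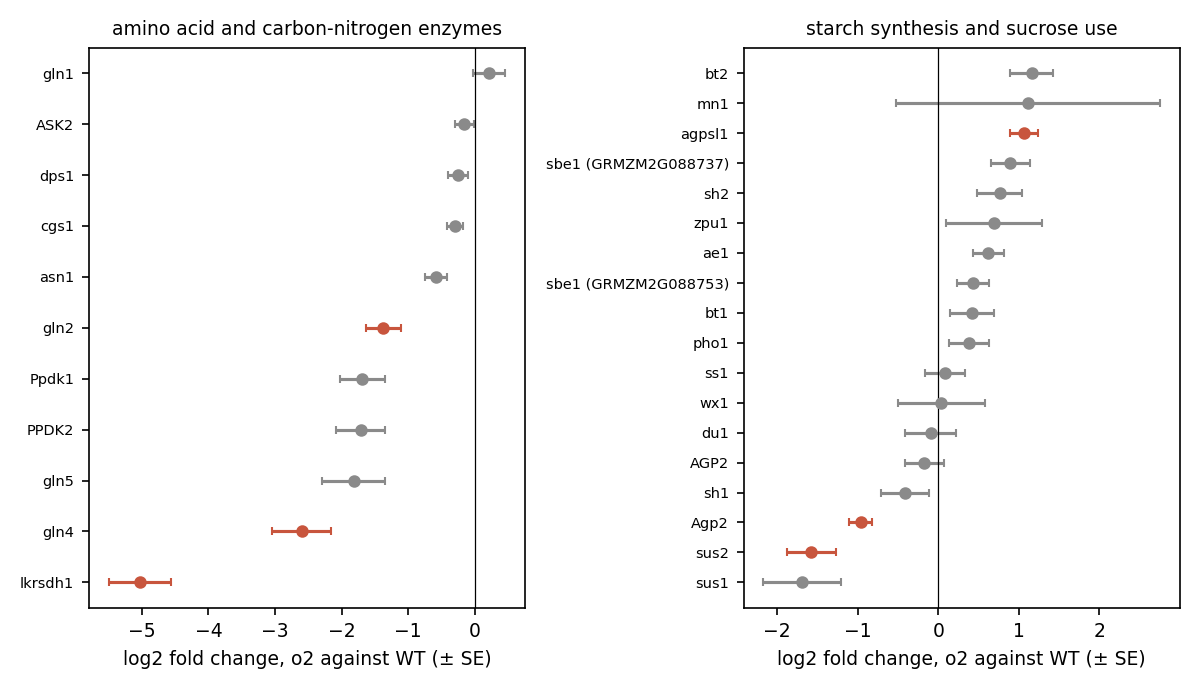
Log2 fold change in o2 against WT on the log2(RPKM + 0.1) scale for the tested genes of the list of amino acid and carbon-nitrogen enzymes (left) and the starch list (right), with the SE of the limma fit as bars and called genes in red. The first list runs from -5.04 for lkrsdh1 to 0.22 for gln1, and the starch list from -1.69 for sus1 to 1.16 for bt2.

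Genes of starch synthesis and sucrose use went both ways. Of 18 tested, 2 fell, 1 rose and 15 were not called, and 3 fell and 4 rose when adjusted over the list alone. The sucrose synthase gene sus2 (GRMZM2G318780) went from 53.2 ± 19.2 to 17.0 ± 2.5 RPKM (SD, n = 3 each; adjusted p = 0.0453) and the ADP-glucose pyrophosphorylase gene Agp2 (GRMZM2G106213) from 9.98 ± 0.884 to 5.07 ± 0.524 RPKM (SD, n = 3 each; adjusted p = 0.0221). Another gene of that enzyme, agpsl1 (GRMZM2G163437), rose from 26.1 ± 3.52 to 54.3 ± 3.02 RPKM (SD, n = 3 each; log2 fold change 1.06, adjusted p = 0.0282). The 4 most abundant members were not called. The granule-bound starch synthase gene wx1 had 1329 ± 631 RPKM in WT and 1318 ± 573 in o2, the sucrose synthase gene sh1 1089 ± 143 and 818 ± 117, and the ADP-glucose transporter gene bt1 666 ± 38.7 and 892 ± 110 (SD, n = 3 each; adjusted p 0.981, 0.515 and 0.474). The ADP-glucose pyrophosphorylase small subunit gene bt2 had 446 ± 59.2 and 989 ± 11.9 RPKM (SD, n = 3 each; adjusted p = 0.0700). All 4 were called higher under quantile normalization and under the total without zein lists (adjusted p up to 0.0336 and 0.0239). The total without zein lists moved the median log2 fold change of all tested genes to 2.08 and called 17895 genes higher. A call in that fit thus does not set a gene apart from genes in general, and sh1 lay below its median gene. With eBayes without trend bt2 was also called (adjusted p = 0.0129). Camera gave an adjusted p of 0.461 for the list, and fry 0.0169 upward. With 1 library left out, sus2 was called only without WT replicate 1, agpsl1 only without WT replicate 2 and Agp2 only without WT replicate 2 or 3 (adjusted p up to 0.167, 0.127 and 0.0958 in the other fits). Under the total without zein lists sus2 and Agp2 turned to 0.54 and 1.13, below the median gene of that fit, and with the replicate block neither they nor agpsl1 were called (adjusted p up to 0.0973).

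Among 7 tested endosperm transcription factor IDs, 2 of them of pbf1, o2 and Nkd2 fell and 0 rose in limma, with 2 lower and 1 higher at an unadjusted p under 0.05 and also when adjusted over the list alone. Nkd2 (GRMZM5G884137), a naked endosperm gene of aleurone development, went from 7.0 ± 2.21 to 2.75 ± 0.567 RPKM (SD, n = 3 each; log2 fold change -1.29, adjusted p = 0.0476). Its duplicate Nkd1 (GRMZM2G129261) had 15.9 ± 6.79 and 20.9 ± 1.28 RPKM (SD, n = 3 each; adjusted p = 0.505). The prolamin-box binding factor gene pbf1 (GRMZM2G146283) had 18 ± 1.81 RPKM in WT and 35.4 ± 10.7 in o2 (SD, n = 3 each; adjusted p = 0.115). A second ID of pbf1 (GRMZM2G146267) had 4.87 ± 1.17 and 5.17 ± 0.357 RPKM (SD, n = 3 each; adjusted p = 0.821). The O2 heterodimerizing protein gene ohp1 (GRMZM2G016150) had 5.74 ± 0.575 and 5.23 ± 0.225 (SD, n = 3 each; adjusted p = 0.653). With the mutated o2 gene in the list, camera gave an adjusted p of 0.233 and fry 0.00249, both downward like the mean log2 fold change of -1.19, whereas the median was 0.11. The other 6 IDs had a mean of 0.04 and a median of 0.11, with adjusted p = 0.966 in camera and 0.797 in fry, an alternative chosen after seeing the data. With 1 library left out, Nkd2 was called only without WT replicate 3 (adjusted p up to 0.166 in the other fits), and it was not called with the replicate block (adjusted p = 0.0868) or with eBayes without trend (adjusted p = 0.0502). Under the total without zein lists it turned to 0.78, below the median gene of that fit.

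Of 7 tested genes for endoplasmic reticulum chaperones and protein folding, 1 fell, the disulfide isomerase gene pdi3 (GRMZM2G134889), chosen after its values were seen, from 5.86 ± 0.621 to 2.89 ± 0.369 RPKM (SD, n = 3 each; adjusted p = 0.0238). The chaperone genes bip1, bip2 and crt2 had log2 fold changes of -0.46, -0.54 and -0.87 (adjusted p 0.464, 0.374 and 0.151), and the disulfide isomerase gene pdi2 had 0.43 (adjusted p = 0.518). Of 4 protein body and opaque or floury genes, 1 fell, z1A1_6 (GRMZM2G353272), which is itself a 19-kDa zein gene. FL1, O10 and o7 had log2 fold changes of -0.21, 0.38 and -0.11 (adjusted p 0.813, 0.682 and 0.880). Adjusted over the list alone, 1 gene fell in each of these lists, and camera adjusted p-values were 0.0881 for the chaperones and 0.233 for the protein body genes. Of 2 tested defence genes, rip1 (GRMZM2G063536), which encodes a ribosome-inactivating protein of the endosperm, went from 29.9 ± 19.1 to 0.0369 ± 0.0235 RPKM (SD, n = 3 each; log2 fold change -7.57, adjusted p = 0.000777), and the chitinase gene chiB had a log2 fold change of 0.37 (adjusted p = 0.802). With 1 library left out, pdi3 was called only without WT replicate 2 (adjusted p up to 0.0912 in the other fits) and z1A1_6 was lost without WT replicate 1 or o2 replicate 2 (adjusted p up to 0.0824), and under the total without zein lists pdi3 turned to 1.07, below the median gene of that fit. With the replicate block pdi3 was not called (adjusted p = 0.0778).

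Markers of other cell types were measured in the same libraries. Of 9 basal transfer layer markers, 0 were called in limma and 0 had an unadjusted p under 0.05, with a wide spread within each genotype. BETL1 (GRMZM2G082785) had 126.5, 39.9 and 2.94 RPKM in WT replicates 1 to 3 and 31.4, 130.04 and 14.03 RPKM in the o2 replicates. The 5 embryo markers fell as a list (camera adjusted p = 0.0260; adjusted p = 0.329 with an estimated correlation) with 0 genes called in limma, 3 lower at an unadjusted p under 0.05 and 2 lower when adjusted over the list alone. The oleosin genes ole1 and ole17 had log2 fold changes of -2.85 and -2.48 (adjusted p 0.108 and 0.124), while the most abundant member, the globulin gene glb3, had 0.48 (adjusted p = 0.685). Of 5 aleurone markers 1 fell, Nkd2, also when adjusted over the list alone, with a camera adjusted p of 0.715 downward like the mean log2 fold change of -0.11, whereas the median was 0.13. The aleurone markers a2 and dek1 had log2 fold changes of -0.03 and 0.13 (adjusted p 0.964 and 0.792). The basal transfer layer list had a camera adjusted p of 0.679, which became 0.0114 downward without WT replicate 3 and 0.0425 upward without WT replicate 1. The embryo adjusted p was 0.0730 without WT replicate 2, 0.0897 without WT replicate 3 and 0.0859 under quantile normalization.

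Heat shock, replication and housekeeping genes held 0 calls in limma. At an unadjusted p under 0.05, 0 of 11 heat shock genes passed, 2 of 3 histone and replication genes were higher, and 2 of 12 housekeeping genes were lower and 3 higher, with 0 in each list adjusted over the list alone. The heat shock gene hsp18a had 136 ± 136 RPKM in WT and 70.9 ± 27.2 in o2, and Hsp70 had 156 ± 102 and 101 ± 62.2 (SD, n = 3 each; adjusted p 0.766 and 0.639). The histone gene histone2b1 had 52.7 ± 30.3 and 105 ± 35.6 RPKM (SD, n = 3 each; adjusted p = 0.25). The glyceraldehyde-3-phosphate dehydrogenase genes gpc3 and gpc4 had 478 ± 322 and 343 ± 221 RPKM in WT and 1384 ± 460 and 1048 ± 439 in o2 (SD, n = 3 each; adjusted p 0.158 and 0.169), and EF1A, a translation elongation factor gene, 208 ± 77.2 and 214 ± 30 (SD, n = 3 each; adjusted p = 0.913). Camera gave adjusted p-values of 0.355 for the heat shock, 0.0881 for the replication and 0.715 for the housekeeping genes, the last downward like their median log2 fold change of -0.15, whereas the mean was 0.12 and fry pointed upward (adjusted p = 0.967). The replication list passed without WT replicate 2 (adjusted p = 0.00503).

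Zein genes also formed the only family by symbol stem that passed. The stem azs had 8 of 9 tested genes lower, against 56 of 1151 genes with a stem (one-sided Fisher's exact test, adjusted p = 1.98e-08). These 9 genes all belong to the 22-kDa alpha zein list, so this restates its fall and adds no separate support. The estimated correlation within that list was 0.922, whereas the test takes genes as independent. Among the higher genes, 10 in this background, 0 of 60 families passed and 1 had an unadjusted p under 0.05 by the same test.

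O2 binding was described by 6365 peaks on the 10 chromosomes of B73 RefGen_v3. The peaks had a median length of 195 bp (range 160 to 1245) and a median fold enrichment of 4.47 (range 1.47 to 22.5). The 5 peaks of highest −log10 q lay on chromosome 5 at 189990711 to 189991420 (−log10 q 74.1, fold 12.3), 188262194 to 188263138 (73.3, fold 13.8) and 36522462 to 36523153 (71.9, fold 14.2), on chromosome 3 at 16551674 to 16552419 (71.6, fold 14.8) and on chromosome 8 at 9649527 to 9650706 (71.4, fold 12.8). Peaks ran from 2.67 per Mb on chromosome 4 to 3.64 per Mb on chromosome 7. Of all peaks, 15.4% had another summit within 10 kb, against a mean of 6.03% and a highest value of 7.42% in 1000 sets of uniform positions, a ratio of 2.56. Among the 3182 peaks of higher −log10 q the share was 9.46% against a uniform mean of 3.10%, a ratio of 3.05. Among the 636 highest it was 9.91% against 0.659%, a ratio of 15.0. The share itself was thus lower in these stricter sets than among all peaks. The uniform mean fell more steeply than the share, so the ratio rose. The cause of this rise was not tested. The densest group held 10 summits within 77.8 kb on chromosome 4, from 5098105 to 5175884. With each chromosome span divided into 3 equal parts, the central parts held 27.4% of the peaks (exact 95% interval 26.3 to 28.5). Uniform positions ignore gene density and mappability, and the genes at these peaks were not analysed here.

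**Figure D3:**
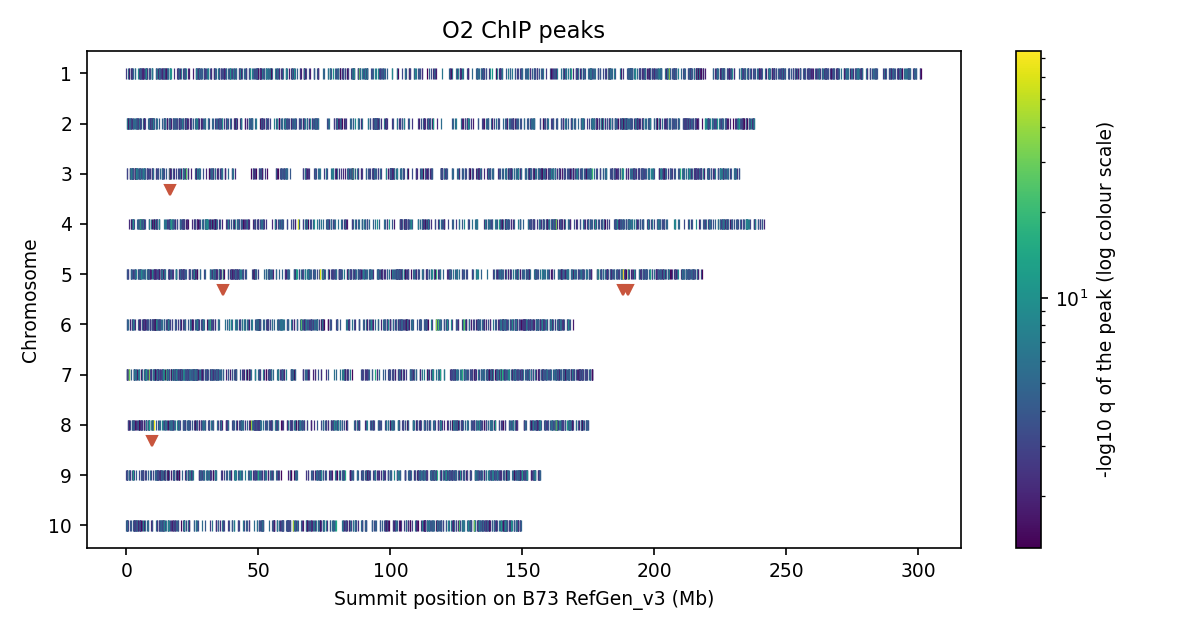
Position of the 6365 O2 ChIP peak summits on the 10 chromosomes of B73 RefGen_v3 in Mb, coloured by −log10 q on a log scale from 1.32 to 74.1, with triangles under the 5 peaks of highest −log10 q. The 5 lie on chromosomes 3, 5 and 8.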

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

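The alternatives without replicate 3 of both genotypes, with members as matched by symbol, with parallel IDs counted once, with a total without the zein lists and parallel IDs and with the transcription factor list without the o2 gene were chosen after seeing the data, and the rest before. The o2 gene kept its direction and its call under every alternative run, with log2 fold changes from -9.04 to -6.60, as did the camera calls of the 19-kDa, 22-kDa and fixed alpha zein lists and of the amino acid and carbon-nitrogen list, except with an estimated correlation.

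Without a filter on low values 1051 genes were called (588 lower, 463 higher, 790 of 2-fold or more), as more genes were tested. With RPKM of 5 or more the counts were 322, 180, 142 and 253 in the same order, as 5879 genes were tested. With the replicate block they were 340, 197, 143 and 339, with 294 of the 666 calls shared. Without replicate 3 of both genotypes they were 299, 157, 142 and 299, with fewer samples. With a total without the zein lists they were 17999, 104, 17895 and 17999, as that scaling moved the median gene to 2.08, and 239 of the 666 calls changed sign. With 1 library left out, the counts ran from 98 to 777, the lower from 84 to 378, the higher from 14 to 399 and those of 2-fold or more from 98 to 550. Pseudocounts of 0.01 and 1 gave 632 and 700 calls, median scaling 700, quantile normalization 779, eBayes without trend 681 and robust 689. Of the 666 called IDs, zein or not, 56 ran parallel to another called ID within 2%. Counting each such group once gave 636. A total without the zein lists and the IDs parallel to zeins gave 654 calls. Its median log2 fold change was -0.03, and 0 of the 666 calls had the opposite sign.

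With the total without the zein lists these log2 fold changes turned positive by the shift of that scaling: bip1 1.67, bip2 1.59, Nkd2 0.78, a2 2.04, gln2 0.74, gz50 1.58, ohp1 1.95, Hsp70 1.49, hsp70-4 1.72, hsp18a 1.62, FL1 1.91, o7 1.99, sh1 1.72, sus2 0.54, Agp2 (GRMZM2G106213) 1.13, AHAS108 0.34, TAR3 0.61, mde1 0.85, aldh2 0.95, der2 1.025, ALDH7 1.25, pdi3 1.07, BZO2H2 1.07, NAC1 (GRMZM2G014653) 0.82 and AHAS109 0.73, all under its median of 2.08. Under quantile normalization gz27 and sh1 turned from lower and not called to called higher, at 3.11 and 1.69 (adjusted p = 0.0102 and 0.0336). That step gives all libraries the same set of values, assigned by rank. The highest RPKM was 43796 or more in each WT library and 10213 or less in each o2 library. The turn is thus one of rank and not of RPKM, whose mean was lower in o2 for both genes. No further cause was tested. Of 56 called genes followed through the alternatives, 4 of them without a name, 56 were called with the same direction under median scaling, 52 under quantile normalization, 40 with the replicate block and 21 without o2 replicate 2. The calls that ended with the replicate block were those of trh2, agpsl1, GLK44, Nkd2, gln2, gln4, sus2, Agp2, frk2, mde1, aldh2, der2, ALDH7, pdi3, BZO2H2 and INO1. Under quantile normalization trh2, agpsl1, z1B_7 and z1B_8 were not called, and Ppdk1, gpc3, wx1, bt1 and bt2 were, besides gz27 and sh1. Under the total without zein lists gln4, frk1, frk2, INO1 and SnRK2.5 were not called (adjusted p from 0.0529 to 0.843). With robust eBayes z1B_7 and z1B_8 were not called (adjusted p = 0.0624 and 0.0560), with a pseudocount of 0.01 z1B_7 (adjusted p = 0.0515) and with eBayes without trend Nkd2 (adjusted p = 0.0502).

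The adjusted p of the 19-kDa, 22-kDa, fixed alpha zein, amino acid and carbon-nitrogen, beta, gamma and delta zein and embryo lists was 0.192, 0.105, 0.105, 0.0765, 0.329 and 0.329 with an estimated correlation. Under quantile normalization it was 0.956 upward for the beta, gamma and delta zeins, 0.0859 for the embryo markers and 0.0134 for the starch list. With fry it was 0.0938 for the embryo markers, 0.00249 for the transcription factors and 0.0169 for the starch list. With the total without the zein lists it was 1.5e-05 for the transcription factors and 3.0e-06 for the protein body genes, with RPKM of 5 or more 0.0157 for the chaperones, and with the zein lists and parallel IDs left out 0.0347 for the histone and replication genes. The cause of these was not tested. Over the fits that leave out 1 library, the adjusted p ran from 0.0114 (downward, without WT replicate 3) to 0.837 for the basal transfer layer markers, from 0.00611 to 0.0897 for the embryo markers, from 0.0192 to 0.217 for the chaperones and from 0.00503 to 0.208 for the histone and replication genes.

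The zein share difference was -56.4 percentage points without the 10 highest genes outside the lists, as the total was then smaller, and ran from -26.5 to -23.4 with 1 library left out. With families of 10 or more tested genes 0 passed, as the azs stem has 9. The deviations of same-number replicates correlated across genes at -0.018, 0.061 and 0.32 for replicates 1 to 3, and at up to 0.23 between different numbers. The highest correlation was that of the replicate 3 pair, so a deviation shared by same-number replicates is not excluded. The replicate block was fixed beforehand as an alternative and was not used for the reported values. With the block, 294 of the 666 calls were kept. The alternatives for genes near peaks and for motifs were not run, since no genome or annotation of B73 RefGen_v3 was used here. Depth limits the low genes, where values under 1 RPKM rest on few reads.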

Other observations

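All tests of explanations in this part were chosen after the results were seen, and the single genes given next were chosen after their values were seen and were not tested as a group.

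The bZIP genes bZip112 (GRMZM2G103647) and GBF1 (GRMZM2G011932) went from 11.8 ± 1.74 to 0.539 ± 0.282 RPKM and from 4.94 ± 1.4 to 0.354 ± 0.0272 RPKM (SD, n = 3 each; limma adjusted p 0.00125 and 0.00101), and both were called with each library left out. The acetohydroxyacid synthase genes AHAS108 and AHAS109, of branched-chain amino acid synthesis, had log2 fold changes of -1.78 and -1.34 (adjusted p 0.00965 and 0.0113). The fructokinase gene frk1 had -2.94 (adjusted p = 0.00714). Without o2 replicate 2, AHAS108, AHAS109 and frk1 were not called, nor was AHAS108 without WT replicate 1 or AHAS109 without o2 replicate 3 (adjusted p up to 0.0699 in these fits). Under the total without zein lists AHAS108 and AHAS109 turned to 0.34 and 0.73, below the median gene of that fit.

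Among genes without a name, GRMZM2G583940 went from 0.603 ± 0.102 to 62.0 ± 3.9 RPKM and GRMZM2G143397 from 0.811 ± 0.779 to 125 ± 43.4 RPKM (SD, n = 3 each; limma adjusted p 3.94e-05 and 0.00231). GRMZM2G044585 and GRMZM2G461650 had log2 fold changes of -10.50 and -10.31. The calls held with each library left out.

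Of the 10 splits of the 6 RNA libraries into 3 and 3, 1 called as many genes as the real one, which is the real one itself, with 666 calls, and the highest other called 1. The splits are too few for a share under 0.05.

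In o2 replicate 3 the 10 19-kDa alpha zeins with a WT mean of 1000 RPKM or more had a median of 8.86 times their level in o2 replicates 1 and 2 (8.44 for z1A and 33.13 for the 2 z1B genes), and the gamma zeins 1.85 to 3.47 times. WT RNA or reads in that library would need a share of 1.05%, but the 22-kDa zeins reached a median of 0.065 of the level that share would bring, and at most 0.076. The median log2 ratio over all tested genes was 0.01, against 0.886 for the smallest rise of a gamma zein. These zeins thus rose relative to the median gene. The deposited columns had near-equal medians, so this value does not test the library scale itself. A difference in stage or dissection that WT replicate 3 shares may contribute: the deviations of both libraries correlated at 0.309 across 18633 genes, which are not independent replicates, and the 9 basal transfer layer markers were lower in both. This cannot be told apart from other differences, since each genotype has 1 such library.

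The 9 22-kDa alpha zeins with a WT mean of 1000 RPKM or more lay at 0.0681% to 0.0903% of their WT level in o2, and z1C1_11, of lower WT level, at 0.108%, next to rip1 at 0.124% and o2 at 0.177%. Of 236 genes with 100 RPKM or more in WT, 0 lay under 0.5 of the median ratio of these zeins, 0.0738%, but these zeins were picked for the largest falls, so this count does not decide on WT reads assigned to o2 libraries. Reads of 19-kDa zeins placed on 22-kDa genes are argued against, since the 22-kDa zeins had a median log2 ratio of -0.076 in o2 replicate 3 where the 19-kDa zeins had 3.15. WT reads and residual transcription of these genes stay open.

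In WT replicate 3 the 9 basal transfer layer markers were all lower than in WT replicates 1 and 2, by a median of 31.6-fold. The median log2 ratio over all tested genes was -0.003, so these markers fell relative to the median gene. As the deposited columns had near-equal medians, this does not test the library scale itself. The 10 aleurone and embryo markers had a median log2 ratio of 0.239 ± 0.694 (SD). This does not decide on a loss of outer and basal tissue together, since 5 of them are embryo markers and the aleurone markers went both ways. Nkd1 was lower, at 8.10 RPKM against 18.9 and 20.6 in WT replicates 1 and 2, as was Nkd2, at 5.3 against 6.19 and 9.49. The markers a2 and dek1 were higher and cr4 lay between. Loss of the basal tissue, alone or with outer tissue, stays open, and no biological explanation was tested.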
